A study of Mus musculus with 3 samples.

How the data were processed

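Naive CD4 T cells from spleen and lymph nodes of C57BL/6 mice, 8 to 12 weeks old and of both sexes, were index-sorted by the authors over the range of surface CD5 into 384-well plates. The gate kept live single cells positive for TCRb, CD4, CD62L and CD5 and negative for CD8, CD25 and CD44. CD5 is a surface protein whose level on a naive T cell follows the strength of tonic T cell receptor (TCR) signals from self-ligands. Single cells were profiled by SORT-seq, a plate form of CEL-Seq2 with a 6-base unique molecular identifier (UMI). Per the labels, reads were mapped with BWA, whose version is not given in the sources used here, to the mouse build mm10.

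The deposited gene table holds expected counts, that is, transcripts estimated by the authors for each gene and cell, for 14355 genes and 84 spike-in transcripts in 697 cells. Of the deposited values, 100% lay within 0.005 of the number of molecules estimated from a whole number of distinct UMIs among the 4096 sequences of 6 bases, and 0.896% were not whole numbers. The authors thus corrected UMI counts for collisions and did not scale them between cells. The deposited CD5 values are a fluorescence signal per sorted cell on the cytometer's scale, with no scaling between plates stated. The authors also placed each cell in a CD5 class, Low, Middle or High. Low cells lay below 26773 and High cells above 69676, the quartiles of all cells together, with 0 exceptions. The rule by which the authors kept cells and genes is not given in the sources used here. The deposited primer sheet holds no measurement and was not used here.

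Each of the 3 labelled samples is a plate, and the plate was taken as the replicate. Nothing in the labels says that the plates come from separate animals, so p-values do not measure spread between animals. With the plate as a block, they measure the spread between sums of cells within these plates, which may be technical. A gene's dispersion was drawn towards that of other genes (38.2 prior against 4 residual degrees of freedom in the class fit). A small p thus need not mean that the plates concur. The counts of all cells of a plate and CD5 class were summed and rounded to whole numbers, which gave 9 sums. All 3 classes shared a dispersion estimate, and the contrast was High minus Low. For the trend, the cells of each plate were ranked by CD5 and summed in 4 bins of equal size, and the slope was taken on the bin's mean log2 CD5. The plate was a block in every fit because the classes of a plate share their library and sequencing. As a check of this pairing, deviations from the class means over 447 abundant genes correlated between the sums of a plate at 0.322 to 0.697.

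Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. Gene lists were tested with edgeR's camera method, which ranks a list against the other genes, at a preset correlation of 0.01 for lists with at least 3 tested genes. An estimated correlation and limma's fry were run beside it. The fry test asks whether a list's genes move in 1 direction on balance and does not compare them with other genes. DESeq2 1.42.0, limma 3.58.1, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used under Python 3.11.15 where Python was needed, with figures from matplotlib 3.10.9. Medians of UMIs per cell were compared within plates by an exact sign-flip permutation test. Variability used cells thinned at random to 2117 UMIs, the 20% quantile of totals, which 557 cells reached. Genes with a mean of at least 0.05 UMIs per cell were compared with a smooth trend of the variance-to-mean ratio on the mean. A gene was selected when its residual lay in the top 5% in each of the 3 plates. List medians were set against 10000 random lists matched on the mean. Binomial intervals are exact (Clopper-Pearson) at 95% and cover counting error only, and a count of 0 is taken to allow up to 3 counts.

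The gene lists, tests, naming rule and a first set of alternatives were fixed before the data were examined. For each comparison the rule names Cd5, then up to 12 genes per direction that passed with the same sign in all 3 plates. Where fewer than 10 passed in a direction, it adds genes of smallest p up to 6, which are said not to pass. It names up to 4 members of smallest p per list and the 20 genes of highest residual for variability. 1 gene that the rule names is not reported here. Izumo1r was found in the table under its older symbol Folr4. The mitochondrial list was meant to be found by the prefix mt-, but the table names most of its protein genes without the hyphen, so its members were taken by chromosome M. Gene positions come from GENCODE M21 on GRCm38, the assembly of mm10, and were found for 13438 genes. Spike-ins, 19.6% of all counts, entered no fit.

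The alternatives fixed beforehand were DESeq2 size factors, the DESeq2 Wald test, no filter, a mean of at least 50 counts, no plate block, cells within 3 times of their plate's median total, cells thinned to 2118 UMIs, mitochondrial and ribosomal protein genes left out, each plate left out, other classes or bins, and other depths and limits for variability. Alternatives chosen after seeing the data left out cells with over 2% of UMIs from Kcnq1ot1, cells with a Foxp3 UMI, or the cell with most UMIs of the Kcnq1ot1 group. Others undid the collision correction or gave each plate 2 cell the CD5 value of the next well number. The fits were tested on simulated sums with the real depths. Each changed gene had the same change in every plate, and no single cell had very high counts. The recovery and false calls of the fits hold for such data, not for a plate that departs from the others or for 1 outlying cell. The class fit, run on 4559 genes, recovered 9.0% of genes changed 1.5-fold, 30.6% of those changed 2-fold and 88.7% of those changed 4-fold, with 1 false call. The trend fit, run on 4720 genes, recovered 67.2%, 94.0% and 100% of genes changed by those folds per doubling of CD5, with 11 false calls. The variability selection, run on 4425 genes, found 29 of 174 genes made variable, with 3 false among 32 selected, and 11 of 11 with a mean of at least 1 UMI.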

Results

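The data hold 697 naive CD4 T cells in 3 plates, with 172, 201 and 324 cells in plates 1, 2 and 3. Each cell has a transcript count per gene and the CD5 fluorescence recorded when it was sorted. The authors' classes hold 174 cells with Low CD5, 349 with Middle and 174 with High. Median CD5 was 16646.5 units in the Low class, 45073 in the Middle class and 89856 in the High class. The cells held 3244019 UMIs in all, with 726230, 1113632 and 1404157 in plates 1, 2 and 3, and a median of 3749, 5449 and 3952 UMIs per cell. Cd4 transcripts were found in 95.7% of cells (95% interval 93.9 to 97.1) and Cd3e in 80.6% (77.5 to 83.5). Genes read from chromosome M took 14.4% of UMIs, genes for cytosolic ribosomal proteins 18.5% and the ribosomal RNA precursor Rn45s 3.29%. Rn45s took 5.16% in plate 2, against 2.09% in plate 1 and 2.43% in plate 3.

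Whether cells with high CD5 hold less RNA than cells with low CD5 is left open by 3 plates. Median UMIs per cell averaged 4597 in the Low and 3872 in the High class, a mean log2 ratio of -0.31 (SD 0.42, n = 3 plates, exact sign-flip permutation p = 0.5, two-sided). The plates gave -0.73, 0.12 and -0.32. Mean UMIs per cell were lower in the High class in 3 of 3 plates, at -0.10, -0.06 and -0.10 (mean log2 ratio -0.09, SD 0.022). Genes detected per cell gave -0.20 (SD 0.29). UMIs per spike-in molecule gave -0.12 (SD 0.29). The median over cells of the mitochondrial share was higher in the High class in 3 of 3 plates, with a mean log2 ratio of 0.12 (SD 0.028, exact p = 0.25), and that of the ribosomal protein share was lower in 3 of 3, at -0.04 (SD 0.032, exact p = 0.25). Of summed UMIs the mitochondrial share was not higher in every plate, with 12.89% in the Low and 12.78% in the High class of plate 2. With 3 plates this exact test cannot give a p below 0.25.

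The comparison of the High with the Low class asks which transcripts differ between naive cells at the ends of the range of self-reactivity. Cd5, the gene of the sorted protein, rose 3.25-fold, from 137 ± 116 to 417 ± 192 CPM (summed counts scaled to library size; SD, n = 3 plates; log2 fold change 1.70, SE 0.30, adjusted p = 0.0022). Cells with a Cd5 UMI made up 23.6% of the Low class (95% interval 17.5 to 30.6), 40.4% of the Middle class (35.2 to 45.8) and 56.3% of the High class (48.6 to 63.8). Folr4, which encodes a folate receptor family protein found on regulatory and anergic T cells, rose 2.24-fold, from 127 ± 53.6 to 276 ± 55.6 CPM (log2 1.16, SE 0.26, adjusted p = 0.0243). Fam78a fell to 0.499 of its Low level, from 349 ± 34.2 to 172 ± 40.3 CPM (log2 -1.0, SE 0.22, adjusted p = 0.0243). Cd5 lies on chromosome 19 at 10717116 to 10739002 and Fam78a on chromosome 2 at 32050055 to 32084857 (mm10).

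The other 6 genes past the threshold all rose, by 1.49-fold to 1.90-fold, and they vary together from cell to cell. They are A130077B15Rik (log2 0.93, SE 0.19), Vmn2r55 (0.69, SE 0.13), Grk4 (0.69, SE 0.15), Kcnq1ot1 (0.61, SE 0.10), A630089N07Rik (0.58, SE 0.10) and Gm17821 (0.57, SE 0.10). Kcnq1ot1 is a long antisense RNA of an imprinted region on chromosome 7. Kcnq1ot1, Gm17821 and Grk4 were higher in 2 of 3 plates, so they fall outside the naming rule and are named after their values were seen. These genes belong, as does Gm10785, to a group of 8 whose share of a cell's UMIs correlates with that of Kcnq1ot1. The Spearman value was 0.57 or more over the cells of all 3 plates together, the next gene reaching 0.39, so differences between plates can enter it. The group's share of summed UMIs rose from 1.27% to 2.34% between the classes of plate 1, and was 1.10% and 1.11% in plate 2 and 1.65% and 3.08% in plate 3. A single High cell of plate 3 held 4380 of the 9574 UMIs it contained in this group, and without it the High share of plate 3 was 1.65%. Without that cell the 6 genes no longer passed.

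**Figure D1:**
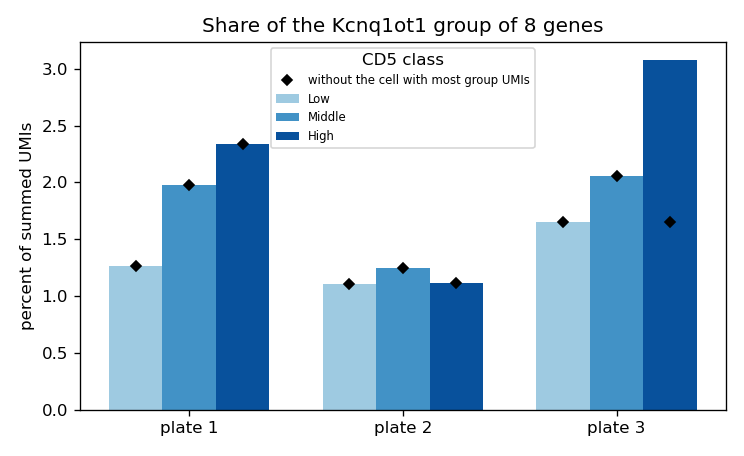
Bars show the share of summed UMIs, in percent, taken by the 8 genes of the Kcnq1ot1 group in each plate and CD5 class, and diamonds show it without the cell that holds most of the group's UMIs. The High bar of plate 3 drops from 3.08% to 1.65% without that cell.

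In all, edgeR tested 4813 genes and 9 passed, 8 higher and 1 lower in the High class, while 297 had an unadjusted p under 0.05. With no difference at all, a share of 0.05 of the tested genes would have such a p, so these counts are not numbers of changed genes. The DESeq2 Wald test called 0 genes, with 147 at an unadjusted p under 0.05, and edgeR without the plate block called 0, with 199. The plates differed in what they showed: the log2 ratio of Cd5 was 2.68, 0.06 and 2.66 in plates 1, 2 and 3, that of Folr4 1.42, 0.48 and 1.57, and that of Fam78a -1.26, -0.66 and -1.12. Without plate 2 edgeR called 20 genes, 16 higher and 4 lower, among them all 9. Without plate 1 or plate 3 it called 0, with 287 and 278 genes at an unadjusted p under 0.05. Without the top cell of the Kcnq1ot1 group only Cd5 passed, and Folr4 (log2 1.14) and Fam78a (log2 -1.02) kept their size without passing. Over 19 alternatives their adjusted p ranged from 0.00012 to 0.997 for Folr4 and 0.0069 to 0.778 for Fam78a.

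**Figure D2:**
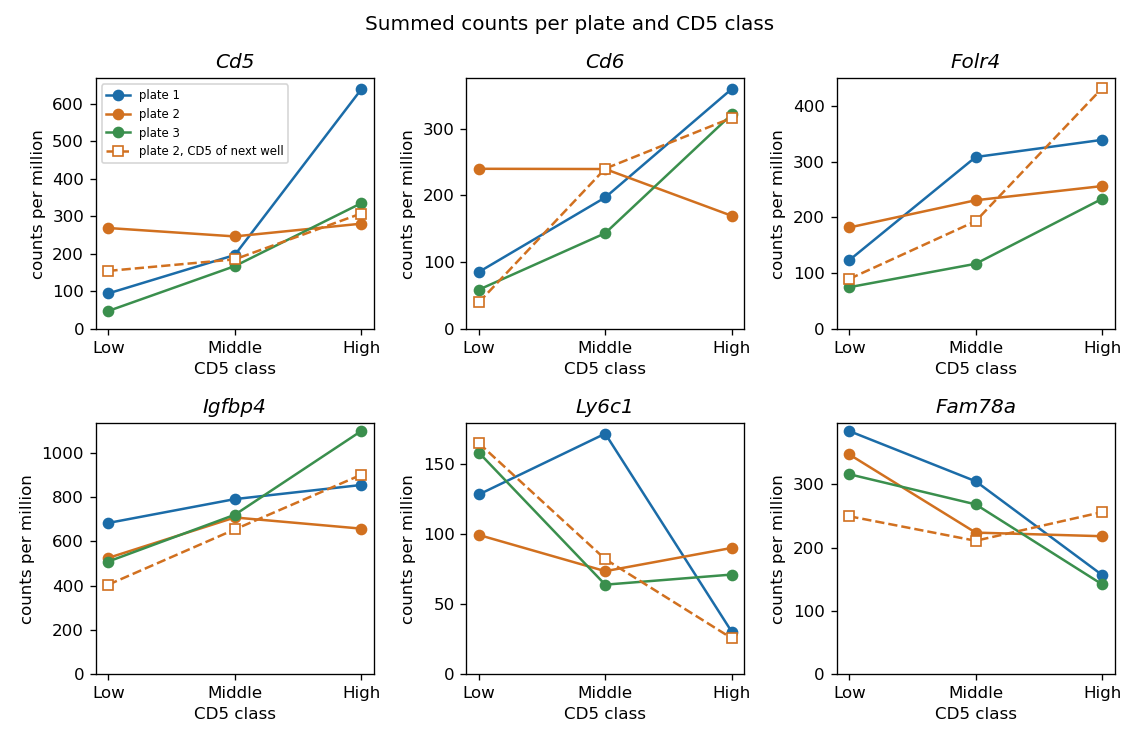
Each panel plots 1 gene's CPM, summed over the cells of each plate, against CD5 class, with a line per plate. Open squares show plate 2 with each cell given the CD5 value of the next well number. Cd5 and Cd6 climb with class in plates 1 and 3, while in plate 2 with the deposited CD5 values Cd6 goes from 240 to 170 CPM.

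The same gap shows cell by cell. The Spearman correlation of Cd5 mRNA with CD5 fluorescence over the cells of a plate was 0.39 in plate 1, 0.08 in plate 2 and 0.26 in plate 3, and that of Cd6 mRNA was 0.22, -0.13 and 0.30. With each cell of plate 2 set against the CD5 value of the next well number, a displacement picked after the data were seen, the correlation was 0.32 for Cd5, 0.37 for Cd6 and 0.31 for Folr4. As deposited Folr4 had 0.17, 0.07 and 0.08 in plates 1, 2 and 3, and of 61 displacements 0 ranked 3 in plate 1 and 7 in plate 3, so it does not peak at 0 there as Cd5 and Cd6 do.

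**Figure D3:**
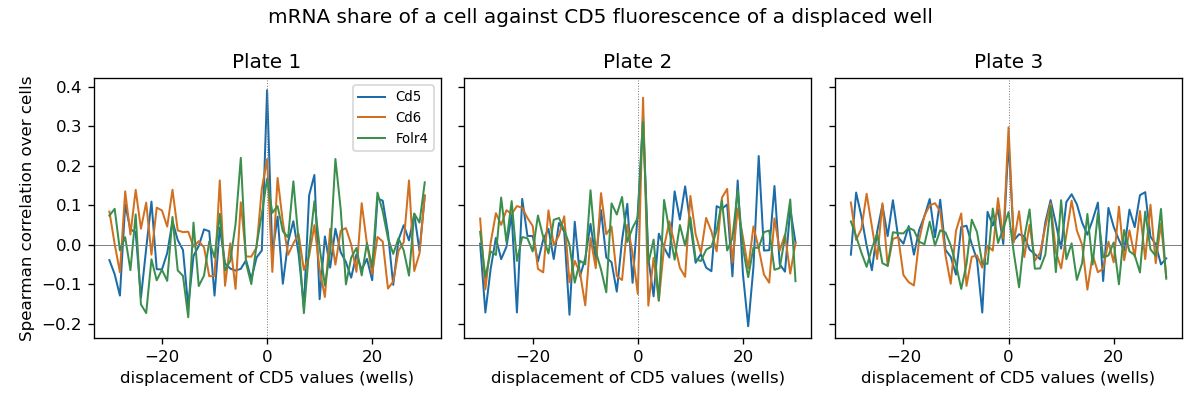
Lines give the Spearman correlation over cells between a gene's share of mRNA and the CD5 fluorescence of a well from 30 back to 30 forward, for Cd5, Cd6 and Folr4 in each plate. In plates 1 and 3 the lines of Cd5 and Cd6 peak at 0, and in plate 2 at 1 well forward.

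The next genes in order of p did not pass. Cd6, a lymphocyte scavenger receptor and relative of Cd5, had a log2 fold change of 1.26 (SE 0.31, adjusted p = 0.0996), with 2.0 in plate 1, 2.34 in plate 3 and -0.49 in plate 2. Igfbp4 had 0.61 (adjusted p = 0.0708), Igf2r 1.61 (0.120), Tmsb4x, which encodes an actin-binding peptide, 0.24 (0.120), Psat1, an enzyme of serine synthesis, 2.61 (0.138) and Gm10785 0.65 (0.114). On the lower side, Pvr had -1.74 (adjusted p = 0.0593), Apc, a regulator of Wnt signalling, -1.73 (0.0996), Wbp11 -1.56 (0.120), Glrx -2.11 (0.303), Rhoh -0.74 (0.303) and Gm14085 -1.14 (0.303).

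The trend over CD5 level uses the whole range of fluorescence rather than its ends. Cd5 rose with each doubling of CD5 by 0.65 on the log2 scale (SE 0.11, adjusted p = 0.0021). Its slopes were 0.93, 0.12 and 0.91 in plates 1, 2 and 3, so 0.65 averages over plates that differ. Its level went from 129 ± 103 CPM in the lowest to 418 ± 209 in the highest bin (SD, n = 3 plates). Cd6 rose by 0.52 per doubling (SE 0.12, adjusted p = 0.0430), with slopes of 0.84 in plate 1, 0.89 in plate 3 and -0.13 in plate 2, so it too falls outside the naming rule. A130077B15Rik (0.35), Vmn2r55 (0.24), Kcnq1ot1 (0.23), A630089N07Rik (0.22) and Gm17821 (0.21) rose too, each with a positive slope in 3 of 3 plates. In plate 2 these slopes ran only from 0.03 for Gm17821 to 0.14 for A130077B15Rik. Without the top cell of the group, which lies in plate 3, none of these genes passed. Folr4 had a slope of 0.45 (SE 0.12, adjusted p = 0.193) and Bcl2, a survival factor, 0.24 (0.616), and neither passed, nor did Grk4 (0.23), Gm10785 (0.22) or Aim1 (0.53). Pvr had -0.67 (adjusted p = 0.0621), Fam78a -0.31 (0.367), Gm14085 -0.40, Zfp653 -0.77, Cpm -0.55 and Wbp11 -0.46, and none of these passed. In all, edgeR tested 4996 genes and 7 passed, all higher with CD5. An unadjusted p under 0.05 was found for 241, no more than the share of 0.05 that would arise with no difference. The DESeq2 Wald test called 3, edgeR without the plate block 0 (180 at an unadjusted p under 0.05), and edgeR without the top cell of the Kcnq1ot1 group 1, which was Cd5. Without plate 2 it called 14, and without plate 1 or plate 3 it called 0, with 267 and 216 at an unadjusted p under 0.05.

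Ly6 genes, which encode small lipid-anchored surface proteins, were the list that stood lowest in High cells. All 3 tested members were lower in 3 of 3 plates: Ly6a, known as Sca-1, at a log2 fold change of -0.85 (SE 0.30), Ly6c1 at -0.95 (SE 0.38) and Ly6e at -0.29 (SE 0.13). Ly6c1 was found in 35.1% of Low, 20.9% of Middle and 19.5% of High cells (95% intervals of Low and High 28.0 to 42.6 and 13.9 to 26.2), and Ly6a in 32.8%, 30.7% and 28.7% (25.8 to 40.3 and 22.1 to 36.1). None passed over all genes, and 3 of 3 fell when adjusted over the list alone. The list passed by camera (adjusted p = 0.0011) and did not with an estimated correlation (adjusted p = 0.408 with an estimated correlation) or by fry (adjusted p = 0.420).

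The lists of genes linked to chronic self-antigen and anergy and of regulatory T cell markers stood higher in High cells. Of 6 tested genes of the self-antigen list, 1 rose and 5 did not pass, both over all genes and adjusted over the list alone, and 6 of 6 had a positive log2 fold change. They include Folr4, Tnfrsf18 (GITR, log2 1.17, SE 0.61), the transcription factor Tox (0.71, SE 0.42) and Nt5e (CD73, 0.54, SE 0.74). Of 5 tested regulatory T cell markers, Folr4 rose and 4 did not pass, over all genes or adjusted over the list alone, among them Foxp3, the lineage's transcription factor, at 0.84 (SE 0.68). Both lists hold Folr4, Tnfrsf18, Nt5e and Ikzf2, so they are not independent. Each passed by camera (adjusted p = 0.0025). Neither did with an estimated correlation (adjusted p = 0.396 with an estimated correlation for each) or by fry (adjusted p = 0.158 and 0.214 by fry). Foxp3 UMIs were found in 9.77% of Low, 5.73% of Middle and 10.9% of High cells, and in 0 cells of plate 1.

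Lists on TCR signalling and on the naive state gave smaller shifts. Of 27 genes of quiescence and lymph node homing, 19 were positive, and Igfbp4 (log2 0.61), Bcl2 (0.72) and Dapl1 (0.76) rose when adjusted over the list alone, while 24 did not pass (camera adjusted p = 0.0509). Of 25 negative regulators of TCR signalling, Cd5 and Cd6 rose when adjusted over the list alone, Cd5 alone rose over all genes and 23 did not pass (0.163). Of 9 T follicular helper genes, Rgs10 (0.74), a regulator of G protein signalling, rose when adjusted over the list alone and 8 did not pass, among them Icos (1.04) and Asap1 (0.77), with a list p of 0.0548. Of 23 listed transcription factors and early genes induced by TCR signals, 11 had enough counts to be tested, and 0 of these passed. Of the 11, 7 were positive, with Myc at 0.96, Tnfaip3 at 0.53 and Nfatc1 at -0.81 (0.185). Of 26 genes of the TCR complex and proximal signalling, 0 passed, with Prkcq at 0.44 and Cd3g at 0.27 (0.791), and this list's median (-0.02) and mean (0.05) differ in sign. Of 4 markers of recent thymic emigrants, 0 passed and 4 were positive, with Itm2a at 0.72 and Tox at 0.71 (0.0853). Here and in the next paragraph counts are adjusted over the list alone unless said otherwise, and 0 genes other than those named passed over all genes. For every list the counts cover tested genes only. Members not found or with too few counts were not tested, so the counts say nothing about them.

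Lists on metabolism, translation and the cytoskeleton did not pass. Of 76 cytosolic ribosomal protein genes 0 passed, with 51 negative and Rpl4 at a log2 fold change of -0.17 (camera adjusted p = 0.185). Of 77 nuclear-encoded respiratory chain genes 0 passed, with Ndufa4 at 0.66 (0.791). Of 15 genes of the mitochondrial genome, mtNd5 rose (0.22) and 14 did not pass (0.585). Of 11 glycolysis genes 0 passed, with Tpi1 at 1.62 and Pgk1 at 0.57 (0.465). Of 38 chromatin regulators 0 passed, with Bcl11b at 0.32 (0.585). Of 29 genes of actin and integrins Tmsb4x rose (0.24), Rhoh fell (-0.74) and 27 did not pass (0.521). Of 39 type I interferon response genes 0 passed, with Ddx60 at -1.41 and Ifi35 at -1.54 (0.646). Of 20 stress and heat shock genes 0 passed, with Hspa5 at 0.67 and Fos at -0.33 (0.791).

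Lists of effector programmes and of other cell types did not pass either. Of 4 T helper 1 genes 0 passed, with Stat4 at a log2 fold change of -0.75 (camera adjusted p = 0.671), and its median (0.02) and mean (-0.12) differ in sign. Of 3 T helper 2 and T helper 17 genes 0 passed, with Il4ra at -0.68 (0.392). Of 10 memory markers 0 passed, with Icos at 1.04 and Lgals1 at -0.44 (0.997), and its median (-0.09) and mean (0.03) differ in sign. Of 9 cycling markers 0 passed, with Hmgb2 at 0.56 and Stmn1 at -0.70 (0.997). Lists with fewer than 3 tested genes had no list test. These were NK cells (Klrd1, 0.39, not past), myeloid cells (Cst3, 0.39, and Ctss, 0.21, not past) and sex genes. The 1 tested sex gene, Xist, had -0.61, with -0.87, -0.44 and -0.50 in plates 1, 2 and 3. Its edgeR adjusted p was 0.773 over all genes. Its unadjusted p was 0.0233, and with 1 tested gene there is no adjustment over the list alone. CD8 T cell, B cell and erythroid lists had 0 tested genes: Cd8a was found in 1.0% of cells, the B cell gene Cd79a in 1.15% and the erythroid gene Alas2 in 0.287%. Of the 21 lists tested, camera passed 3 and an estimated correlation 0, with 2 at an unadjusted p under 0.05, as did fry, with 4 at an unadjusted p under 0.05. Thinned to 1 depth, 1 list passed, and without plates 1, 2 and 3 the numbers were 2, 5 and 1.

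The last question is which genes differ most between single naive cells whatever their CD5. Rn45s varied most for its mean, with a variance-to-mean ratio of 77.2 ± 38.6 (SD, n = 3 plates), followed by Kcnq1ot1 at 34.9 ± 15.6 and Gm17821 at 23.2 ± 10.3. Of the 22 genes in the top 5% in all 3 plates, A630089N07Rik, Vmn2r55, Grk4 and A130077B15Rik belong to the Kcnq1ot1 group too. Mitochondrial transcripts made up a further set, with mt-Rnr2, mt-Rnr1, mtCo1, mtCytb, mtAtp6 and mtNd5. Others were Mir5109, the translation repressor gene Eif4ebp2, Ipcef1, Cdk19, the granule proteoglycan gene Srgn (2.94 ± 0.20), the nuclear RNA Malat1 (3.54 ± 0.73), Sf3b4 and Scd2, the last 2 outside the naming rule and named after their values were seen. Of 4170 genes, 0.521 would be in the top 5% of all plates if the plates were independent. No test was run. At no thinning 29 genes were selected, 9 of them shared, and at the median depth 22 with 12 shared, so the selection depends on depth, and the top 10% held 47.

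**Figure D4:**
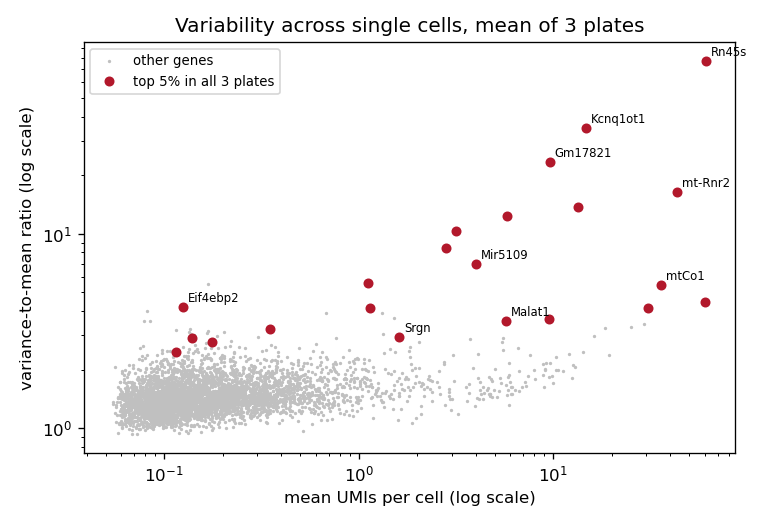
Each point is a gene, with mean UMIs per cell on the horizontal and the variance-to-mean ratio on the vertical axis, both on log scales and averaged over 3 plates. Red points are the 22 genes in the top 5% of residuals in every plate, with Rn45s highest at 77.2.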

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

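Alternatives without the top cell of the Kcnq1ot1 group, with at most 2% Kcnq1ot1, without Foxp3 cells, with observed UMIs and with moved CD5 values in plate 2 were chosen after seeing the data. Against 9 genes between the highest and lowest CD5 class, the count was 0 by the DESeq2 Wald test (147 at an unadjusted p under 0.05), 16 without a filter on low counts, 5 among cells thinned to 1 depth, 2 in cells with at most 2% Kcnq1ot1, 1 without the top cell, and 25 with the CD5 of the next well in plate 2, or 16 when the top cell was left out as well. Leaving out each plate gave 0 to 20, with plate 2 the plate whose absence gave 20. Against 7 genes in the trend, it was 3 by the DESeq2 Wald test, 1 in cells with at most 2% Kcnq1ot1, 1 without the top cell, 11 with 3 bins, 3 with 6 bins, 17 with the CD5 of the next well and 11 without the top cell as well, and 0 to 14 on leaving out each plate. The plate block matters: with no replicate block edgeR called 0 genes in both comparisons (199 and 180 at an unadjusted p under 0.05), while 3 lists passed as before. Against 3 lists, the count was 0 with an estimated correlation, 0 by fry (2 and 4 at an unadjusted p under 0.05), 1 among thinned cells, 5 in cells with at most 2% Kcnq1ot1, 7 with the CD5 of the next well with or without the top cell, and 1 to 5 on leaving out each plate. Against 22 variable genes, the top 10% held 47 and leaving out each plate gave 47 to 53, since fewer plates have to concur. The cause of these shifts was not tested where it is not named.

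The other alternatives kept the counts within 1.5 times: 8 to 11 class genes over 8 of them, 5 to 10 trend genes over 9, 2 to 4 lists over 4, and 16 to 29 variable genes over 4. The UMI ratio ranged from -0.53 to -0.09 over its 7 alternatives, within the spread between plates. Among single genes and lists, 2135 values kept direction and side of the threshold, 118 no longer passed, 71 newly passed, 70 that passed in neither fit changed sign, and 1 reversed: Grk4 in the class comparison, at -0.00857 in cells with at most 2% Kcnq1ot1, where the cells with most of it are left out by construction. Values for which DESeq2 gives no adjusted p are left out. At this depth and with 3 plates, 30.6% of simulated genes changed 2-fold were recovered in the class comparison, and no other depth or number of plates was simulated.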

Other observations

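Tests chosen after their result was seen are those of the top cell of plate 3, of Folr4 without Foxp3 cells, of the splits and of the random assignments, and the gene and list fits with moved CD5 values in plate 2, as are the gene choices in the next 2 paragraphs. The layouts of plate 2 and the test of 100 genes at a displacement of 1 well were set down before they were run.

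Some gene lists varied together from cell to cell. Among cells thinned to 1 depth, the mean pairwise correlation was 0.188 ± 0.0087 (SD, n = 3 plates) for 14 genes of the mitochondrial genome, 0.125 ± 0.0022 for 75 ribosomal protein genes and 0.053 ± 0.037 for 36 type I interferon response genes, each above all random lists matched on mean in 3 of 3 plates. Ly6a, Ly6c1 and Ly6e gave 0.105 ± 0.035, at or above the 90.2 percentile of random lists, and genes of quiescence and homing 0.023 ± 0.0098, at or above the 98.4 percentile. Actin and integrin genes gave 0.0165 ± 0.0057 (97.8 percentile or above) and chromatin regulators 0.0110 ± 0.0058 (91.1 or above). In variability for its mean, the list of TCR-induced early genes stood at the 100 percentile of random lists and the mitochondrial genome, whose median residual of 0.714 was the highest of all lists, at 99.99. The self-antigen list stood at 99.3, quiescence and homing at 99.1, the interferon response at 97.2, negative regulators of TCR signalling at 95.8, the Ly6 family at 95.4 and chromatin regulators at 93.2, while ribosomal protein and respiratory chain genes stood at 0. Dntt, the template-independent DNA polymerase of developing thymocytes, was too rare for the gene test and goes against the tested members of its list of recent thymic emigrants, all positive in High cells. Its UMIs were found in 13 of 174 Low cells (7.47%, 95% interval 4.04 to 12.4), 4 of 349 Middle cells (1.15%, 0.313 to 2.91) and 1 of 174 High cells (0.575%, 0.0145 to 3.16), with the highest share in Low cells in 3 of 3 plates. Thinned to 1 depth it was found in 6 of 150 Low, 2 of 275 Middle and 1 of 132 High cells.

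The plates differed in how many cells gave UMIs of Foxp3 and of stress genes. Foxp3 UMIs were found in 0 of 172 cells of plate 1, in 8 of 201 of plate 2 and in 48 of 324 of plate 3, where 43 of these cells held 1 UMI, so cells that express Foxp3 without a captured UMI are not counted. The gate excluded CD25, and Il2ra, the gene of CD25, was found in 1.16%, 1.99% and 2.16% of cells. A UMI of Il2ra, Ikzf2, Ctla4 or Gpr83 was found in 6 of 11 cells of plates 2 and 3 with 2 or more Foxp3 UMIs (54.5%, 95% interval 23.4 to 83.3), in 6 of the 43 plate 3 cells with 1 (14.0%, 5.30 to 27.9) and in 18 of 276 plate 3 cells without (6.52%, 3.91 to 10.1). Median UMIs per cell were 6451, 4802 and 3724 in these groups, so the share rose along with depth. In plate 2 it was 0 of 2 cells with 1 Foxp3 UMI and 10 of 193 without. The heat shock gene Hspa1b was found in 4.65%, 4.48% and 35.8% of cells of plates 1, 2 and 3, and the immediate early genes Fosb in 9.88%, 12.4% and 45.7% and Jun in 60.5%, 55.2% and 87.0%. Among cells thinned to 1 depth Hspa1b stood at 2.42%, 1.70% and 26.5%.

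In plate 2, Cd5 mRNA hardly followed CD5 fluorescence: the Spearman correlation over cells was 0.08, against 0.39 in plate 1 and 0.26 in plate 3, and that of Cd6 was -0.13, against 0.22 and 0.30. A turned, mirrored or shifted plate was tried in 14 layouts, and giving each cell the CD5 value of the next well number raised Cd5 to 0.324, above the 0.262 of plate 3, the lower of the other plates. In the test of displacement, 100 genes picked from plates 1 and 3, without the Kcnq1ot1 group and genes looked at before, had a mean signed correlation in plate 2 of -0.0185 as deposited and of 0.0534 at a displacement of 1 well, the highest of 61 displacements (SD of the others 0.0103, highest of them 0.0213). The peak at 1 well argues against CD5 values assigned without order throughout plate 2, which would leave it within the spread of the other displacements. The test made for that came out on the side of such values by its rule. The rule took a mean signed log2 ratio within the range of random assignments to go with them. To go against them, the mean had to lie above nearly all random assignments. Plate 2 gave -0.205, near their low end (989 of 1000 as high). The same statistic did not stand out in plate 1 (0.024) or plate 3 (0.0888; 400 and 123 as high), so failing it in plate 2 does not decide, a reading made after its value was seen. A candidate explanation is that CD5 values and count columns of plate 2 are out of step by 1 well. The design names no biological difference of plate 2. A difference under which its mRNA does not follow CD5 would leave no peak at 1 well. The 0.0534 of the 100 genes there, against at most 0.0213 at the other displacements, argues against it as the sole account for these genes. The sources used here do not say that column numbers are well numbers.

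Under that displacement, plates 1 and 3 keep their values, 170 cells of plate 2 have a next well, 31 are left out and 105 change class. Cd6 then rose by 2.41 between the classes (SE 0.28, adjusted p = 7.3e-06; 2.0, 2.81 and 2.32 in plates 1, 2 and 3), Cd5 by 2.14 (0.96 in plate 2) and Folr4 by 1.78 (2.19 in plate 2). A430093F15Rik, an RNA read from between Cd5 and Cd6 on chromosome 19 (10740947 to 10786043), rose by 2.86. Igfbp4 (0.86), Bcl2 (0.85), Dapl1 (1.25), Smc4 (0.85), Igf2r (2.15) and the protease receptor gene F2rl1 (1.98) rose as well, and Ly6c1 (-1.77), Thy1 (-0.50), Rhoh (-1.0), Gm14085 (-1.77), Usp1 (-1.85) and Wdr92 (-0.55) fell. These 16 genes also passed without the top cell of the Kcnq1ot1 group, whereas Fam78a (-0.78, adjusted p = 0.270) did not pass. In all, 25 genes passed, 19 higher and 6 lower. The 19 other displacements from 10 back to 10 forward, apart from 0, gave a median of 9 and at most 17. The deposited order gave 9 as well. Outside the Kcnq1ot1 group 18 passed, against 3 in the deposited order and at most 10 at the other displacements. The counts of 25 and 18 include Cd5, Cd6, Folr4, Igfbp4 and Ly6c1, looked at when the displacement was found, so they partly restate its choice. The lists that passed were the Ly6 family (down, adjusted p = 1.5e-06), regulatory T cell markers (5.9e-06), self-antigen and anergy (3.4e-05), quiescence and homing (0.00029), ribosomal proteins (down, 0.0095), negative regulators of TCR signalling (0.0101) and recent thymic emigrants (0.0461), and 0 passed with an estimated correlation (lowest adjusted p = 0.111 with an estimated correlation). All of these but ribosomal proteins and recent thymic emigrants hold genes looked at when the displacement was found (Cd5, Cd6, Folr4, Ly6a, Ly6c1 or Igfbp4), so their p partly restates its choice, as do the values of these genes. Without plates 1, 2 and 3 and without the top cell, 3, 8 and 23 genes passed.

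The Kcnq1ot1 group was higher in High cells of plates 1 and 3, with log2 ratios of its share of 0.89 and 0.90. In plate 3, 1 cell with very high counts can account for the difference, since the ratio without it was -0.00157 (SD over draws of cells 0.254). In plate 1 the values argue against a single cell, with 0.805 left without the top High cell (SD 0.320). Cells of few UMIs stay open in plate 1, where 32 High and 39 Low cells thinned to 1 depth gave 0.906 with an SD of 0.468, too wide to decide. The 8 genes lie on several chromosomes, and whether they share a repeat or a priming site was not examined, so the difference in plate 1 may be technical or biological.

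Folr4 marks regulatory T cells, so its rise in High cells may come from such cells in the sort. Without cells that hold a Foxp3 UMI the log2 fold change was 1.32 (edgeR adjusted p = 0.0187; over all 19 alternatives 0.00012 to 0.997). This cannot decide the question, since 43 of the 48 such cells of plate 3 held 1 UMI. Cells that express Foxp3 without a captured UMI stay in. Without the 244 cells that hold a UMI of any of the other 11 markers of the list, the mean log2 ratio was 1.35 (SD 0.47 over plates; 0.81, 1.54 and 1.68), against 1.19 in all cells. In the class fit of all cells the plates gave 1.42, 0.48 and 1.57. Plate 1 was thus lower without the marker cells, and plate 2, whose CD5 values are in doubt, was higher. The rise was not confined to cells with a captured marker UMI. Regulatory T cells whose markers were not captured stay open as a source. A higher level of Folr4 in naive cells with stronger self-reactivity remains a hypothesis, found and tested on the same cells.

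The 6 sums of the highest and lowest classes make 10 splits, too few for a share under 0.05. For genes, 2 of 10 splits gave as many calls as the real split, which gave 9, and the highest other gave 18. That split differs from the real one only in that the classes of plate 2 are exchanged, so it points to a structure of the samples in which plate 2 departs from plates 1 and 3. For lists, 3 of 10 gave as many, with 3 in the real split and 5 in the highest other. Those with 3 and 5 put both classes of a plate on 1 side, against the pairing of the fits, and of the 4 splits that part the classes of all 3 plates only the real one gave any list. When cells were assigned at random to CD5 levels within plates 50 times, 0 draws gave 9 class genes (highest 7), 0 gave 7 trend genes (highest 2), and 5 gave 3 lists (highest 4). Outside the Kcnq1ot1 group 3 class genes passed and 0 draws gave as many (highest 2). Without the top cell of that group, where only Cd5 passed, 8 draws gave 1 or more class genes and 6 gave 1 trend gene. Random assignment thus stays open for the number of lists and, without that cell, for the numbers of genes, though not for Cd5, whose log2 fold change of 1.70 and slope of 0.65 without the cell lay beyond all draws (at most 0.66 and 0.20 from 0). For single lists, the mean log2 fold change lay as far from 0 in 0 draws for the Ly6 family, 2 for the self-antigen list and 5 for regulatory T cell markers. Lists that did not pass by camera lay as far out, with 0 draws for glycolysis and T follicular helper genes, 2 for negative regulators of TCR signalling and 3 for quiescence and homing, as did the sex gene list of 1 tested gene with 2.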
